A study of Rattus norvegicus with 24 samples.

How the data were processed

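Messenger RNA from the heart septum of 24 rats in 4 groups of 6 was sequenced in paired reads, per the labels' protocols. The authors deposited a table of whole-number read counts for 30562 genes, with the start, end, strand and exonic length of each gene. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a and counted with featureCounts 2.0.2, with DESeq2 and R 4.4.1 also named. Per the file header the counts were made with featureCounts 2.0.6 on the Ensembl 113 annotation of mRatBN7.2, in paired-end mode and with no strand or multimapping option, so the version differs between these sources. The header gives no option to count read pairs once. Across the table a count of 2 occurs 19013 times and a count of 4 occurs 12355 times, against 5161 for a count of 1 and 3060 for a count of 3, as when both mates of a pair are counted. The deposited counts are therefore read counts, not counts of fragments, and the spread between libraries used by the models was estimated on that scale. Genes that overlap, lie antisense to each other or share sequence with a copy cannot be separated by such counts. The 5 further count columns that match no listed sample were not used here.

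Groups and replicate numbers came from the labels, which also give each rat a number. No 2 libraries had identical counts. Library totals were 71587993 to 122910706 reads, and counts were used as deposited. Genes were kept by edgeR's filterByExpr on the groups (17347 genes), scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood fit) in R 4.3.3 with all 24 libraries in 1 model, so that the groups share an estimate of the spread, and with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 differences were taken from the quasi-likelihood F statistic. Levels are CPM as edgeR computes it from TMM-scaled library sizes, and principal components used log2 CPM with a prior count of 2. These tests, the alternatives with DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), sva 3.50.0 (1 surrogate variable), other scalings, filters and thresholds, the replicate number as a block, the rat number as a linear covariate and each library left out were fixed before the data were examined.

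The rat-number term (the 7 libraries with the highest rat numbers against the other 17, a boundary read from PC1), the fit to the low-numbered rats alone, the fit with a length gradient per library, the fit without 4 leptin rats, the test of chromosome sets, the analysis of neighbouring genes and the mitochondrial read share were chosen after the data were seen. Other fits looked at while exploring were a linear rat number and the replicate block, both of which had been planned. The length gradient of a library is the median centred log2 CPM of the longest of 5 classes of genes by exonic length minus that of the shortest. Neighbouring genes are consecutive tested genes on a chromosome, their calls being shuffled 1000 times within 10 classes of abundance. Shares were compared by exact two-sided permutation tests.

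A rule for named genes and 39 gene lists had been fixed by gene symbol, with a camera test of each list. The table of gene names at hand paired 0 of the 30562 IDs with a symbol, so the lists, their tests and the symbol rule were not run. In their place 4 IDs are named by a rule chosen after the data were seen: the risen and the fallen gene with the smallest p and a mean of at least 1 CPM, in leptin against vehicle and in BAT ablation against intact BAT. The chromosome stretches named were chosen after their values were seen. For the chromosome sets, limma's camera used a preset correlation of 0.01 and then an estimated one.

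The model was tested on simulated counts with 200 of 17347 genes changed, for leptin against vehicle. Means, dispersions and library sizes were the real ones, the dispersions being estimated with the rat-number term in the model. The first simulation held no rat-number difference and was fitted without the term. It therefore does not describe the fit as designed on the real libraries, whose spread includes that difference. There the model recovered 51% of 100 genes changed by a fold of 2 and 24% of 100 changed by a fold of 1.5, with 5 false calls among 80. With the rat-number difference simulated and its term in the model it recovered 51% and 20%, with 3 false calls among 74. A gene that missed the threshold can therefore still have changed by a fold of 2. Unchanged groups were simulated 4 times with the rat-number difference kept, and the control libraries were split in 20 ways (10 ways per simulation, 5 ways with a library left out). These simulations draw each gene independently and hold no shared variation between genes beyond the rat-number difference.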

Results

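Gene expression was measured by mRNA sequencing in the heart septum of 24 Sprague-Dawley rat hearts, collected on day 28 after cardiac ischemia-reperfusion. The rats formed 4 groups of 6. In the first group brown adipose tissue (BAT, the heat-producing fat depot) was left intact and vehicle was infused into the cerebral ventricles. In the second group BAT was intact and the infusion held leptin, the adipocyte hormone that acts on hypothalamic neurons. The other groups received leptin after ablation of BAT or after its sympathetic denervation. No operated group received vehicle. Each library came from a separately numbered rat, so the spread within a group includes spread between animals. It also includes the difference between sets of rat numbers described below.

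The libraries held 71587993 to 122910706 assigned reads, and reads fell on 17982 to 19730 of the 30562 annotated genes per library. After filtering on low counts, 17347 genes were tested. Reads from the mitochondrial chromosome made up 23.1% to 45.9% of a library, and the most abundant mitochondrial gene alone took 6.53% to 15.1%. The files identify genes by Ensembl rat ID and do not pair the IDs with names, so genes are described by ID, chromosome position on the mRatBN7.2 assembly and level.

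**Figure D1:**
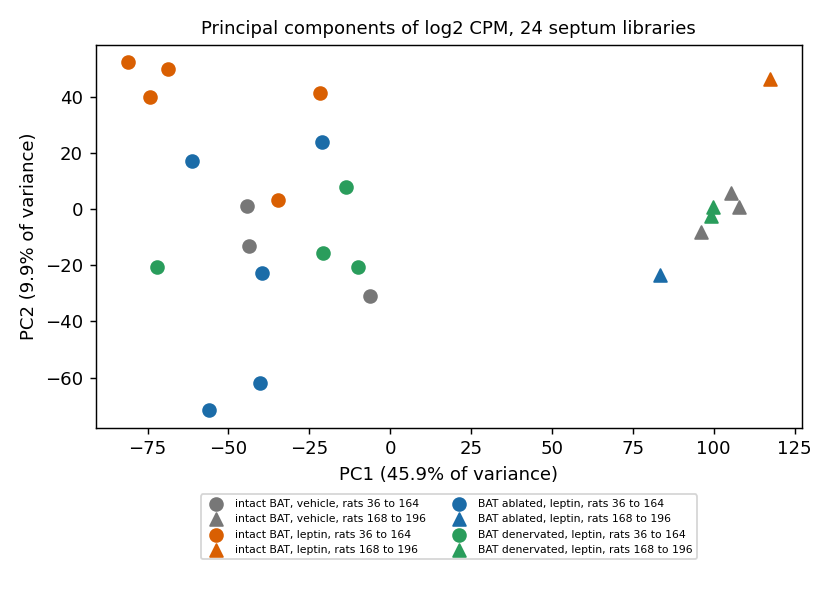
Principal components of log2 CPM for the 24 libraries, each point being 1 library, with colour for the group and triangles for the rats with the highest numbers. The 7 libraries of those rats, which come from all 4 groups, lie at 83.5 or above on PC1, and the 17 libraries of the other rats lie at -6.34 or below.

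The largest difference between libraries did not follow the groups. The first principal component, with 45.9% of the variance, separated the 7 libraries of the rats with the highest numbers (3 vehicle, 1 intact BAT with leptin, 1 BAT ablation and 2 BAT denervation) from the 17 libraries of the low-numbered rats. Between these sets, 11656 of 17347 genes differed at an adjusted p below 0.05 (edgeR quasi-likelihood test), 5753 higher and 5903 lower in the high-numbered rats, with a median absolute log2 difference of 0.97. The boundary between the sets was read from PC1 of these same libraries, which favours a large count. These p values are therefore not independent of the choice. The 10 most abundant nuclear genes took 13.3% ± 0.478 (SD, n = 7) of the nuclear reads in the high-numbered rats and 8.35% ± 2.00 (SD, n = 17) in the others. Because the sets were unequally spread over the groups, each comparison is given as designed and again with a 2-level term for the rat-number set, which was chosen after the data were seen.

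The first comparison asked which septal genes differed between leptin and vehicle when BAT was intact. At an adjusted p below 0.05, 89 genes were higher and 28 lower in leptin-infused rats, and the changed genes had a median absolute log2 difference of 0.99. Across genes this difference correlated at -0.62 with that between the high-numbered and the low-numbered rats, and at -0.14 once the rat-number term was added. The gene with the smallest p among those that rose, ENSRNOG00000018804 on chromosome 17 (40323867 to 40548092, minus strand, exonic length 9035 bp), reached 67.4 ± 9.35 CPM (SD, n = 6) with leptin against 31.1 ± 4.26 CPM with vehicle, a log2 difference of 1.11 ± 0.16 (SE, edgeR adjusted p = 0.00737). Every leptin library (57.4 to 84.6 CPM) lay above every vehicle library (25.2 to 36.8 CPM). The gene was chosen for its small p in these same libraries, which favours such separation. Among the genes that fell, ENSRNOG00000001984 on chromosome 11 (31580742 to 31593901, minus strand, 2064 bp) had 0.258 ± 0.211 CPM with leptin and 2.04 ± 0.789 CPM with vehicle, a log2 difference of -2.97 ± 0.51 (edgeR adjusted p = 0.0316). The call on the chromosome 11 gene was lost in 6 of the 12 fits that each left out 1 library, where the edgeR adjusted p ranged from 0.00674 to 0.0990. No other annotated gene overlapped either position on either strand.

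The genes that rose with leptin were mostly of middle or high abundance. In the class with a mean of 10 to 100 CPM, 55 of 7444 genes rose and 9 fell, and in the class of 100 CPM and over 23 of 1268 rose and 3 fell. In the class of 1 to 10 CPM 11 of 4671 rose and 15 fell, and in the class under 1 CPM 0 of 3964 rose and 1 fell. The share of genes called in either direction also rose with abundance after ablation, from 0.505% under 1 CPM to 6.47% at 100 CPM and over. The rise with abundance is thus not particular to leptin, and recovery by depth was not tested. Of the 22 tested mitochondrial genes, none passed the threshold, with 7 above 0 and 15 below. After adding the rat-number term, 722 genes rose and 341 fell, including all 117 genes called without it. In this fit 532 genes rose and 189 fell in the class of 10 to 100 CPM, 106 rose and 36 fell at 100 CPM and over, 73 rose and 93 fell at 1 to 10 CPM, and 11 rose and 23 fell under 1 CPM. Also in this fit, neighbouring genes on chromosome 17 (43148079 to 43253264, 3 genes) rose together with a median log2 difference of 0.72. A stretch of chromosome 10 (103249363 to 103528877, 3 genes) also rose, by a median of 0.59. Adjacent non-overlapping genes changed in the same direction 44 times, and 63 of 1000 shuffles of the calls among genes of like abundance gave as many. With a length gradient per library also in the model the count of 1063 fell to 428, of which 401 were among the 1063. All 1063 genes kept their direction, at a median log2 difference in that direction of 0.551 (SE 0.155) against 0.646 (SE 0.166) before. Without the gradient the count was 258 to 423 without leptin replicate 1, 2 or 4, 2219 without leptin replicate 5, 98 without vehicle replicate 3 and 476 to 671 without vehicle replicate 2, 4, 5 or 6.

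The count for leptin against vehicle rested on single libraries. It fell to 4 or fewer when leptin replicate 1, 2 or 4 or vehicle replicate 3, 4, 5 or 6 was left out, lay at 53 without leptin replicate 3 and at 193 to 395 without vehicle replicate 1 or 2 or leptin replicate 5, and rose to 4454 without leptin replicate 6. Within the low-numbered rats (5 leptin, 3 vehicle) edgeR called 0 genes, with 3431 at an unadjusted p below 0.05 and adjusted p values of 0.125 and 0.138 for the named genes, while the high-numbered set held only 1 leptin library, and without the 4 leptin rats numbered 56 to 62 the fit with the rat-number term called 18 genes.

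**Figure D2:**
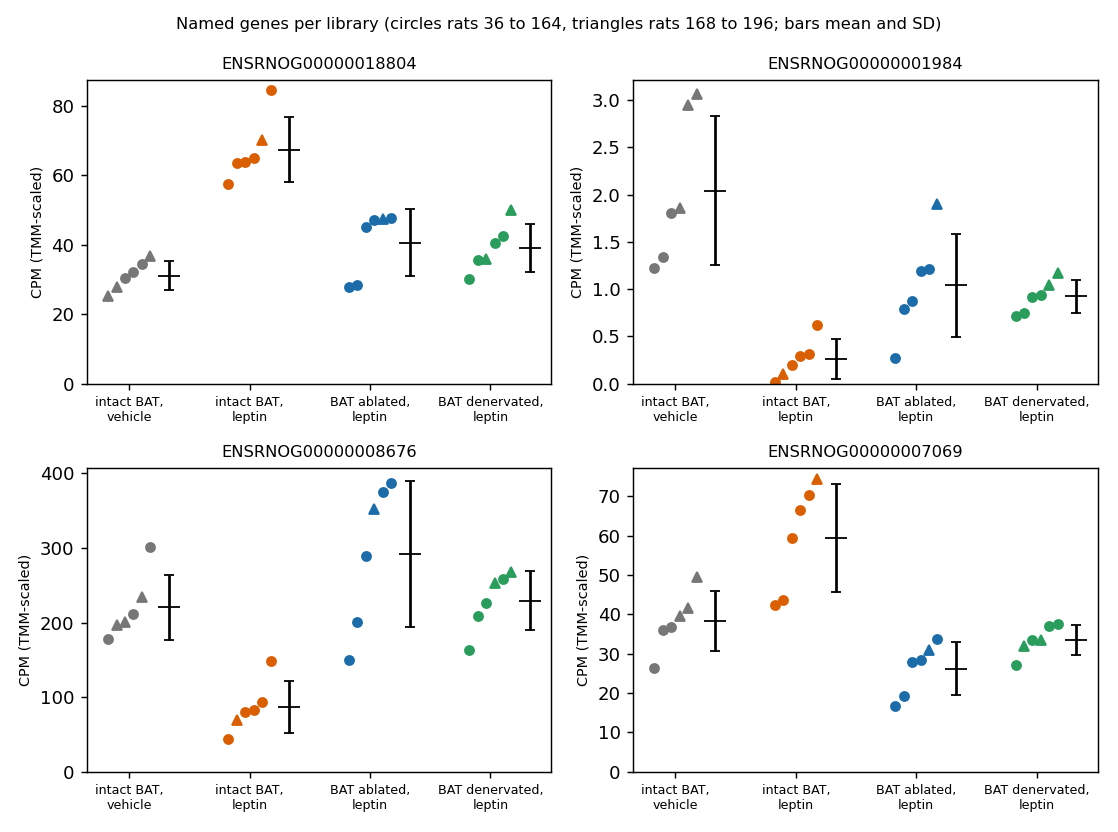
Level of the 4 named genes in each of the 24 libraries, in TMM-scaled CPM on a linear axis from 0, by group, with triangles for the 7 high-numbered rats and bars for the group mean and SD. For ENSRNOG00000018804 and ENSRNOG00000008676 the 6 intact BAT with leptin libraries (57.4 to 84.6 and 44.1 to 149 CPM) do not overlap the 6 vehicle libraries (25.2 to 36.8 and 179 to 301 CPM). Both genes were chosen for small p values in comparisons that use these leptin libraries, which favours such separation.

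The second comparison asked what the absence of BAT changed in leptin-infused rats. BAT ablation raised 323 genes and lowered 202 relative to intact BAT with leptin, with a median absolute log2 difference of 0.85 among the changed genes. The risen gene with the smallest p, ENSRNOG00000008676 on chromosome 4 (168212861 to 168232904, plus strand, 2624 bp), stood at 292 ± 97.9 CPM (SD, n = 6) after ablation and 86.5 ± 34.9 CPM with intact BAT, a log2 difference of 1.76 ± 0.26 (SE, edgeR adjusted p = 0.00828). It was at 221 ± 43.6 CPM with vehicle. The fallen gene with the smallest p, ENSRNOG00000007069 on chromosome 5 (9705970 to 9732517, minus strand, 1907 bp), stood at 26.2 ± 6.70 CPM after ablation and 59.4 ± 13.6 CPM with intact BAT, a log2 difference of -1.18 ± 0.18 (edgeR adjusted p = 0.00828). It was at 38.3 ± 7.56 CPM with vehicle, and its difference between leptin and vehicle did not pass as designed (edgeR adjusted p = 0.073). The gene on chromosome 17 that rose with leptin, ENSRNOG00000018804, was lower after ablation by a log2 difference of -0.73 ± 0.16 (edgeR adjusted p = 0.0224), and the chromosome 11 gene that fell with leptin, ENSRNOG00000001984, was higher by 1.99 ± 0.50 (edgeR adjusted p = 0.0333). Both were chosen for their difference between leptin and vehicle, and this comparison uses the same intact BAT with leptin libraries, which favours the opposite sign, so these p values are not independent of the choice.

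Genes that changed after ablation lay beside each other more often than in shuffled calls. Adjacent non-overlapping genes were called in the same direction 16 times, against a mean of 7.70 in 1000 shuffles within abundance classes, of which 4 gave as many. With the rat-number term 1673 genes rose and 1546 fell, including all 525 genes called without it, and with a length gradient per library also in the model 1295 were called, 1217 of them among these 3219. Without the gradient there were 389 such neighbouring pairs against a mean of 272 and a maximum of 330 in the shuffles. Stretches of at least 3 consecutive tested genes called in 1 direction then numbered 60, of which 28 were higher and 32 lower. The count of 3219 was 1652 to 2131 without ablation replicate 1 or 3 or leptin replicate 1 or 2. The longest stretch lay on chromosome 9 (76117168 to 76304959), where 8 consecutive genes were lower after ablation, by log2 differences of -0.88 to -0.48. On chromosome 12 (45880440 to 46320357) 5 genes were lower by a median log2 difference of -0.39. On chromosome 1 (208243559 to 208414758) 4 genes were higher by 1.03 to 1.29, and on chromosome 5 (148897246 to 149136534) 4 were higher by 0.86 to 1.95. On chromosome 7 (85566520 to 86324827) 3 genes were higher by a median of 1.56. Reads were counted without strand, and the 8 chromosome 9 genes lay in 7 non-overlapping blocks and the 5 chromosome 12 genes in 4.

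Transcript length went with the direction of the ablation difference. The median log2 difference moved from 0.04 in the fifth of genes with the shortest exonic length (36 to 1548 bp) to -0.11 in the fifth with the longest (4817 to 113560 bp). No difference in the gradient between these classes was shown between the 2 groups at the level of libraries (-0.149, exact permutation p = 0.323, two-sided, n = 6 per group). Within the low-numbered rats the difference was -0.189 (exact permutation p = 0.127). The gradient followed the rat-number sets, at -0.172 ± 0.157 (SD, n = 17) in the low-numbered and 0.343 ± 0.104 (SD, n = 7) in the high-numbered rats. The trend in the medians was not particular to this comparison. As designed, they moved from 0.02 to -0.07 for leptin against vehicle and from 0.13 to -0.09 for ablation against vehicle. With the rat-number term they moved the other way for leptin against vehicle, from -0.06 to 0.03. Of the 22 mitochondrial genes 0 were called for ablation against intact BAT, 6 being above 0 and 16 below.

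The ablation count also depended on single libraries and on which groups entered the model. It was 7 to 41 without ablation replicate 1 or 3 or leptin replicate 1 or 2, 138 to 236 without ablation replicate 2 or leptin replicate 3 or 4, and 808 to 1037 without ablation replicate 4 or 5 or leptin replicate 5 or 6. It was 2033 in the low-numbered rats alone (5 and 5 libraries), 5 with the rat-number term and without the 4 leptin rats numbered 56 to 62, and 0 when only the 12 libraries compared entered the model, with 2344 genes at an unadjusted p below 0.05 by edgeR and an adjusted p of 0.214 for both named genes.

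The third comparison asked what sympathetic denervation of BAT changed in leptin-infused rats. As designed, edgeR called 0 genes, with 2836 at an unadjusted p below 0.05, and DESeq2 called 433 and limma-voom with sample weights 3955. Evenly spread p values would give 867 below 0.05. Genes are not independent and this fit leaves the rat-number difference unmodelled, so 867 does not bound what chance gives. The 4 named genes did not pass the test as designed, and all 4 passed with the rat-number term. ENSRNOG00000008676 stood at 230 ± 39.5 CPM (SD, n = 6) and ENSRNOG00000007069 at 33.5 ± 3.80 CPM, with log2 differences of 1.41 ± 0.25 and -0.83 ± 0.18 (edgeR adjusted p = 0.109 and 0.112). The rat-number term gave 1.40 ± 0.25 and -0.86 ± 0.16 for them (edgeR adjusted p = 0.0145 for both). ENSRNOG00000018804 differed by -0.78 ± 0.16 as designed and -0.80 ± 0.15 with the term (edgeR adjusted p = 0.109 and 0.0145), and ENSRNOG00000001984 by 1.83 ± 0.49 and 1.67 ± 0.47 (edgeR adjusted p = 0.131 and 0.0378). All 4 genes were chosen in comparisons that use the same intact BAT with leptin libraries, so these p values are not independent of the choice. In the model with the rat-number term 422 genes rose and 732 fell, and with a length gradient per library also in the model 2 of these 1154 genes stayed called. All 1154 kept their direction, at a median log2 difference in that direction of 0.49 (SE 0.15) against 0.61 (SE 0.16) before. Without the gradient, stretches of at least 3 neighbouring genes numbered 8, of which 6 were lower after denervation. On chromosome 11 (67877967 to 68001495) 4 genes were lower by a median log2 difference of -1.56, on chromosome 2 (60865483 to 61020436) 3 genes were higher by 1.42, and the 3 chromosome 17 genes that rose with leptin were lower by 0.42 to 0.72. Neighbouring pairs numbered 66, above the maximum of 56 in 1000 shuffles. As designed, the count was 31 without leptin replicate 5, 647 without leptin replicate 6 and 17 without denervation replicate 1, and within the low-numbered rats (4 and 5 libraries) 1 gene passed. With the rat-number term it was 49 to 105 without leptin replicate 1, 2 or 4 or denervation replicate 2 or 3, 1 without denervation replicate 4, 426 to 453 without denervation replicate 5 or 6, 1697 to 2329 without leptin replicate 3, 5 or 6 or denervation replicate 1, and 5 without the 4 leptin rats numbered 56 to 62.

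Mitochondrial RNA took a smaller mean share of the reads in denervated rats than in the other 3 groups. The mitochondrial chromosome took 26.7% ± 1.97 (SD, n = 6) of reads after BAT denervation, 35.2% ± 1.17 with intact BAT and vehicle, 33.5% ± 5.35 with intact BAT and leptin, and 34.7% ± 8.24 after BAT ablation. The difference from vehicle was -8.54 percentage points, with every denervated library below every vehicle library (exact permutation p = 0.00216, two-sided, the smallest that 6 libraries against 6 allow, adjusted p = 0.013 over 6 comparisons). Against intact BAT with leptin the difference was -6.77 points (exact permutation p = 0.013, adjusted p = 0.039), and ablation stood 7.98 points above denervation, a difference that did not hold after adjustment or in 10 of 12 tests that each left out 1 library (exact permutation p = 0.0498, adjusted p = 0.0996). Within the low-numbered rats the differences of denervation were -9.36 points from vehicle (exact permutation p = 0.0286) and -6.57 points from leptin (exact permutation p = 0.0635). Within the high-numbered rats they were -7.60 points, where 2 libraries against 3 cannot give an exact permutation p below 0.1, and -8.15 points. The mean log2 difference of the 15 most abundant mitochondrial genes, TMM-scaled, was -0.66 against vehicle (exact permutation p = 0.00866) and -0.42 against intact BAT with leptin, where it did not pass (exact permutation p = 0.119). All 22 tested mitochondrial genes lay below 0 against intact BAT with leptin (median log2 difference -0.44), and 20 of 22 lay below 0 against vehicle (median -0.64). Tested by camera among 23 chromosome sets with a preset correlation, the mitochondrial set was lower in both comparisons (adjusted p = 2.16e-05 and 2.68e-21). With an estimated correlation of 0.492 between its genes, neither call held (adjusted p = 0.597 and 0.0614).

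**Figure D3:**
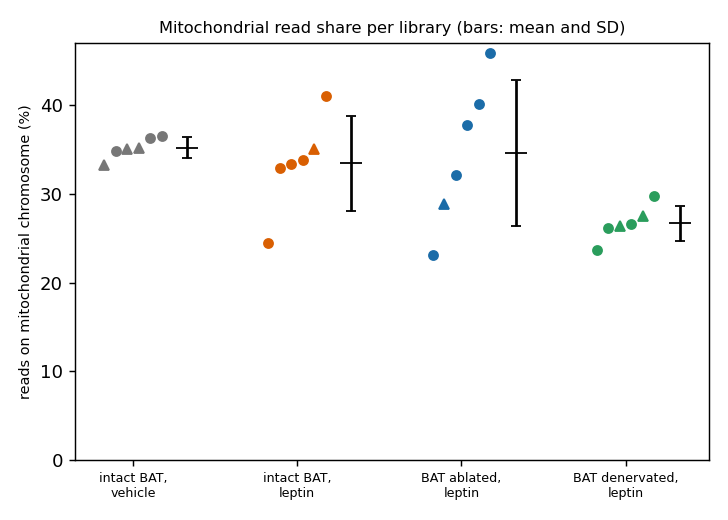
Share of each library's reads on the mitochondrial chromosome, in percent, by group, with circles for the 17 low-numbered rats, triangles for the 7 high-numbered rats and bars for the mean and SD. The 6 denervated libraries lie between 23.7% and 29.8%, below the 6 vehicle libraries at 33.3% to 36.6%.

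Most genes selected for a leptin difference had the opposite sign in the BAT comparisons. The comparisons share the intact BAT with leptin libraries, so these were split 3 and 3, genes being selected at p below 0.01 in one part against vehicle (a median of 729 genes over 20 splits) and tested with the other part. Of the selected genes a median of 87.7% had the opposite sign after BAT ablation (45.3% to 92.5% over the splits), where simulated unchanged groups gave 34.7% to 38.5%. After BAT denervation the median was 90.7% (68.8% to 94.0%), against 49.0% to 56.5% in the simulations. The simulations hold no variation shared between genes beyond the rat-number difference, so their ranges do not show how far such shares vary by chance. Both parts of every split also held some of the leptin rats numbered 56 to 62. A condition shared by those rats would therefore not be removed by splitting. With no operated group on vehicle, an effect of the operations alone is not separated from leptin's effect either. Of the 89 genes that rose with leptin 46 fell after ablation, and of the 28 that fell 15 rose. Those counts share the intact BAT with leptin libraries, which favours such an overlap, and its size without a BAT effect was not estimated.

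The effects of ablation and denervation were correlated across genes (Pearson r = 0.66, genes not being independent replicates), with a covariance of 0.229 against 0.0661 to 0.07 in simulated unchanged groups that share the same control libraries. The simulated groups gave an r of 0.44 to 0.46 from the shared libraries alone. The measured r fell to 0.43 without ablation replicate 6, the only high-numbered rat of its group. No simulation left out that library, so this value has no simulated range of its own to be set against. With the control libraries split, r had a median of 0.17 (-0.15 to 0.40 over the splits) and the covariance 0.0882, against -0.0023 to 0.00604 in the simulations. The median r after splitting, once the rat-number term was added, was 0.36 (0.13 to 0.43), against -0.01 to 0.02 in the simulations, and without splitting r was 0.73 against 0.49 to 0.51. Because the simulations lack variation shared between genes beyond the rat-number difference, their ranges do not show how far r or the covariance varies by chance. Splitting also left some of the leptin rats numbered 56 to 62 in both parts, so a condition they share could contribute to these values.

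The remaining comparisons set the BAT-operated groups against vehicle and against each other. For BAT ablation with leptin against vehicle, edgeR called 0 genes, with 1892 at an unadjusted p below 0.05, and DESeq2 called 20 and limma-voom 9663. For BAT denervation with leptin against vehicle, edgeR called 0, with 348 at an unadjusted p below 0.05, and DESeq2 called 0 and limma-voom 8051. Between ablation and denervation edgeR called 0, with 778 at an unadjusted p below 0.05, and DESeq2 called 0 and limma-voom 54. Evenly spread p values would give 867 in each comparison, so 1892 lay above that number and 348 and 778 below it. ENSRNOG00000018804 lay between vehicle and intact BAT with leptin in both operated groups, at 40.6 ± 9.69 CPM after ablation and 39.1 ± 6.87 CPM after denervation (SD, n = 6), and its log2 differences from vehicle were 0.38 ± 0.16 and 0.33 ± 0.16 (SE, edgeR adjusted p = 0.457 and 1.00). Adding the 2-level rat-number term, edgeR also called 0 genes in each of these 3 comparisons, with 1487, 659 and 1482 at an unadjusted p below 0.05. With the rat number as a linear covariate it called 6804 genes for ablation against vehicle, 0 for denervation against vehicle and 3392 for ablation against denervation.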

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

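The explanations weighed here were tested after the results were seen, while the tests on other splits of the samples had their predictions written before their outcomes were known.

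The highest PC1 value of the intact BAT with leptin group was 117 in replicate 6, where the nearest other library lay at -21.7, and that of the BAT ablation group was 83.5 in replicate 6, where the nearest lay at -21.0. The TMM scaling factor of leptin replicate 6 was 0.699, against 0.993 to 1.11 in the other 5. These 3 values stood far from the rest of their group, among 36 sets of 6 libraries tested, where chance gives about 1 in 20, or 1.8. All belong to the only high-numbered rat of their group. The mitochondrial read share after ablation stood 7.98 points above that after denervation in a direct test (exact permutation p = 0.0498, two-sided, n = 6 per group), which did not hold after adjustment (adjusted p = 0.0996) or in 10 of 12 tests that each left out 1 library.

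The first pattern is the separation of the 7 libraries of the high-numbered rats from the others. Group accounted for 14.6% of the variance of PC1, depth is argued against by 3 high-numbered libraries with totals inside the range of the others and PC1 values of 83.5 or more, and without the 100 most abundant genes the number set still accounted for 91.1% of it. A candidate explanation is a batch of animals or libraries that follows rat number, which accounted for 91.1% of PC1, but the boundary between the sets was drawn from these libraries. The labels give no date or batch, and no biological explanation was tested.

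The second pattern is the distance of the intact BAT with leptin libraries from the other groups. An effect of leptin that needs BAT is a biological explanation. No BAT-operated group received vehicle, so such an effect of leptin cannot be told apart from an effect of the operations alone. A shared condition of leptin rats 56 to 62 may be another explanation. On 3286 genes selected with those 4 rats against vehicle, leptin replicates 5 and 6 scored 0.10 and 0.20, below denervation replicate 1 and ablation replicate 4 (0.28 and 0.27), and no difference from the 12 operated libraries was shown (exact permutation p = 0.286, 91 regroupings). An earlier form of the check, counted over genes, pointed the other way, with 72.9% and 71.9% of the genes opposite in sign to ablation and denervation against at most 50% and 52.7% in simulations, but those simulations lack variation shared between genes, so the explanations cannot be told apart. Transcript length bias as the whole cause is argued against for ablation, where 1217 of 3219 genes stayed called with a length gradient in the model. For denervation 2 of 1154 stayed called. All 1154 kept their direction, their median log2 difference moving from 0.61 (SE 0.16) to 0.49 (SE 0.15), where that for ablation moved from 0.64 to 0.51. What ended the calls was not tested, and length bias remains open.

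The third pattern is the lower mitochondrial read share after denervation, for which loss of BAT innervation is a biological explanation and remains untested against sampling. Ablation, which removes BAT itself, showed no such difference: 34.7% ± 8.24 (SD, n = 6) against 33.5% ± 5.35 with intact BAT and leptin (exact permutation p = 0.777). The spread after ablation was wide, and its difference from denervation did not hold after adjustment, so this does not settle the question. The difference between the number sets is argued against by the low-numbered rats alone (exact permutation p = 0.0286 against vehicle), and a single abundant gene by the share without it (exact permutation p = 0.00216, the smallest possible). RNA quality or tissue sampling could also lower the share. The length gradient, an indirect measure of it, gave an exact permutation p of 0.515 against vehicle, which does not exclude it.

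Other splits of the 12 libraries into groups of 6 were drawn to 100 per comparison, the real one included. For leptin against vehicle 5 gave at least the real 117 genes, so chance is not excluded, and the highest, 7637, set 4 high-numbered libraries against 0, a structure of the samples and not of the groups. For ablation against intact BAT 2 gave at least 525 (highest other 1604), a share under 5% with no adjustment over the comparisons. For the comparisons with 0 calls by edgeR, which have 2836, 1892, 348 and 778 genes at an unadjusted p below 0.05 (DESeq2 called 433, 20, 0 and 0, limma-voom 3955, 9663, 8051 and 54), a real count of 0 fixes the outcome at 100 of 100 splits, so the splits say nothing about chance there. Their highest other counts were 5234, 2570, 6951 and 13. With the rat-number term and the sets kept balanced, 1 split gave at least 1063 genes for leptin (highest other 638). For ablation 3 gave at least 3219 (highest other 4257) and for denervation 4 gave at least 1154 (highest other 2856), so some regroupings called more genes than the real groups. Each share lay under 5% with no adjustment over the comparisons. Because the term was also chosen after the data were seen, these splits do not exclude chance.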

How the results depend on the processing

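The rat-number term, the length gradient, the low-numbered rats alone, the fit without leptin rats 56 to 62 and all tests of the mitochondrial share were chosen after the results were seen. Of 418 alternative values 5 reversed in sign, all differences in mitochondrial share that had not passed the test and that each left out 1 library. Gene counts, which are among these values, cannot reverse in sign, so the 5 do not describe them, and their changes are given below. Counts below are for leptin against vehicle, ablation against intact BAT and denervation against intact BAT (117, 525 and 0 as designed), and the cause was not tested unless stated.

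An adjusted p threshold of 0.10 gave 1213 and 1165 in the first 2, DESeq2 1538, 1267 and 433, and limma-voom with sample weights 10526, 3022 and 3955. For leptin, median-ratio scaling gave 204, upper-quartile scaling 33 and a minimum of 1 CPM 225. Without a low-count filter, which adds tested genes, the counts were 3 and 234. The replicate block gave 3635, 1021 and 512, a linear rat number 1069, 4042 and 13, 1 surrogate variable 1582, 4342 and 1706, the rat-number term 1063, 3219 and 1154, and that term with the length gradient 428, 1295 and 2. The labels do not say what the replicate number marks. Within each group it rose with rat number, except for leptin replicate 4 (rat 56), so the block partly stands in for rat number. Same-numbered libraries did not all deviate together. Across genes, which are not independent replicates, their correlations ranged from 0.144 to 0.491 for replicates 1 and 2 and from -0.340 to 0.706 for replicates 3 to 5. For replicate 6 (all 4 from high-numbered rats) they ranged from 0.652 to 0.730. Of 24 libraries 9 correlated best with their own number, and the number that chance gives was not estimated. The low-numbered rats alone gave 0, 2033 and 1, the fit without leptin rats 56 to 62 gave 18, 5 and 5, and only the 2 groups compared 6 and 0, each with fewer libraries. At 0, edgeR had 3431 and 2344 genes at an unadjusted p below 0.05.

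Against vehicle, ablation was called in 20 genes by DESeq2, 9663 by limma-voom, 1 with the replicate block and 6804 with a linear rat number, and denervation in 8051 by limma-voom. Ablation against denervation gave 54 by limma-voom and 3392 with a linear rat number.

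With each library left out in turn the counts ranged from 1 to 4454 for leptin, from 7 to 1037 for ablation, from 0 to 647 for denervation and from 0 to 2 for ablation against vehicle, and stayed at 0 in the other 2 comparisons. Opposite-sign shares, for which only the vehicle and operated libraries and none of the intact BAT with leptin libraries were left out, ranged from 83.7% to 90.7% for ablation and for denervation. The correlation of the 2 BAT effects ranged from 0.43 without ablation replicate 6 to 0.77, and was 0.17 with the control libraries split.

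The difference in mitochondrial share ranged, with each library left out, from -9.16 to -7.95 points for denervation against vehicle, from -8.58 to -5.25 against leptin, from 5.74 to 10.3 for ablation against denervation (10 of 12 no longer below an exact p of 0.05), from -3.29 to 0.0425 for leptin against vehicle, from -1.03 to 3.53 for ablation against leptin and from -2.80 to 1.76 for ablation against vehicle. In the low-numbered rats alone it was -6.57 for denervation against leptin (exact permutation p = 0.0635) and 9.25 for ablation against denervation (exact permutation p = 0.103). The tests of gene lists and their variations were not run. In the class under 1 CPM, 3964 genes gave 1 call for leptin as designed, and recovery by depth was not tested.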

Other observations

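The rat-number term was chosen after the data were seen.

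With the rat-number term, 569 of the 722 genes that rose with leptin fell after ablation and 389 fell after denervation. Of the 341 that fell with leptin, 278 rose after ablation and 175 after denervation. Ablation and denervation shared 322 risen and 568 fallen genes. The comparisons have the intact BAT with leptin libraries in common, which favours such overlaps, and their size without a BAT effect was not estimated.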
